A study of Arabidopsis thaliana with 16 samples.

How the data were processed

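RNA of Arabidopsis thaliana inflorescences was compared on 16 two-colour Agilent microarrays. The plants were ap1-1 cal-1 double mutants carrying 35S:AP1-GR, a constitutively expressed fusion of the floral regulator AP1 to the glucocorticoid receptor, which dexamethasone activates. Per the labels, tissue of about 25 plants aged about 4 weeks, grown at 20 °C in constant light, was pooled for each sample. It was treated with 10 µM dexamethasone (Dex), a mock solution (Mock), 10 µM cycloheximide (CHX), an inhibitor of protein synthesis, or both compounds (DexCHX), and collected after 3 h. All solutions held 0.01% ethanol and 0.015% Silwet. There were 4 biologically independent sets, numbered 3 to 6. Each set gave 4 hybridisations, Dex vs Mock, CHX vs Mock, DexCHX vs Mock and DexCHX vs CHX, so that each comparison rests on n = 4 arrays. The first-named RNA was in Cy3 in sets 3 and 5 and in Cy5 in sets 4 and 6.

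The deposited scanner files hold, per the file headers, the median intensity of each spot and of its local background in both dyes, as read by Feature Extraction 10.1.1.1. They also hold the processed intensity, which the authors' software corrected for background and for dye within each array, and a log10 ratio of the processed Cy5 over Cy3 intensity. The value table deposited by the authors holds the same log10 ratio averaged over the spots of a probe. Its sign is turned so that the first-named RNA is the numerator, which was tested on the values. The plan named the mean spot intensity, but the deposited files hold only the median intensity, which was used instead. Depth on an array is signal over background. Between 48.6% and 58.5% of probes had a spot well above background in Cy3, and between 51.1% and 79.9% in Cy5. No spot was saturated, and 314 spots marked by the software as non-uniform or as outliers were masked. The number of arrays limits the precision.

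Each array held 45210 spots, of which 1417 were control spots, and 43643 probes. Of these, 36953 carried a locus name, covering 28327 loci, of which 27785 were found in the gene table of the reference assembly TAIR10.1. Per the file headers the array used an older build (ath1), and genes were joined by locus name, with no coordinates used. Spots of one probe were averaged. A probe was kept if it was well above background in at least 4 of its 32 channel measurements, and the kept probe with the highest mean intensity stood for its gene, which left 21288 genes. The 6682 probes without a locus name were left out of the comparisons and tested apart.

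Median intensities were corrected with normexp (offset 50), turned into log2 ratios and normalised by loess within each array. A linear model in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) was fitted to all 16 arrays, with 1 coefficient per hybridisation type and 1 dye effect per gene, which left 11 residual degrees of freedom. Arrays of a set share RNA, so these degrees of freedom are not fully independent, which the model does not take into account. A gene was called when its two-sided p from limma, adjusted by Benjamini-Hochberg over all genes, was under 0.05. The difference between the DexCHX vs CHX and Dex vs Mock ratios was tested as a contrast in the same model. The overlap of both comparisons was set beside the product of their shares, and the direct DexCHX vs CHX ratio beside the indirect one, DexCHX vs Mock minus CHX vs Mock. On simulated data with known changes, the model recovered between 64.2% and 80.6% of genes changed by 0.5 on the log2 scale and between 95.5% and 98.5% of those changed by 1. Between 2.65% and 5.10% of its calls were false. The simulated arrays had independent noise, the same spread per gene in every comparison and few changed genes. Real arrays of a set share RNA, so these shares need not hold for the data.

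The set number pairs the samples, because the labels give 1 RNA of each treatment per set and both RNAs of a set meet on each array. In the data, arrays of different types that share the Mock RNA of a set deviated from their type's mean together, with r across genes between 0.295 and 0.652, and between 0.191 and 0.621 with the dye effect, which all arrays of a set share in direction, taken out. The log ratio is therefore already a difference within a set. A block for the set was run as an alternative, and its value is given beside the 1 result that it moves by over 1.5 times.

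Before the data were examined, 19 gene lists were chosen, for floral identity, flowering time, meristem and boundary, organ polarity, gibberellin, auxin, cytokinin, brassinosteroid, jasmonate, rapid stress response, heat shock, clock, mitosis, photosynthesis, vascular, epidermal, stamen, reference and ribosomal protein genes. The model, the threshold, the alternatives (except 3 described with their effects) and the rule for named genes were also chosen before the data were examined. Only 7 ribosomal protein genes were found by name in the gene table. Lists were tested with camera at a preset correlation of 0.01, adjusted over all 95 tests of a list in a comparison, and again with a correlation estimated from the data and with fry. Genes with a masked spot were left out of camera, which left 25 of the 27 measured flowering time genes in it. Genes are named by a rule. For Dex vs Mock, DexCHX vs CHX and CHX vs Mock it takes the 10 called genes with the largest positive and the 10 with the largest negative ratio that changed the same way in all 4 sets. DexCHX vs Mock and the difference take 5 and 5. From each list it takes up to 4 called members with the largest change, or the 2 with the smallest p where fewer than 2 were called, and it always takes AP1 and CAL.

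The alternatives changed the background correction, the normalisation, the source of the values, the filter, the treatment of several probes, the dye effect, blocks for slide and set, the arrays and the form of the model, the variance shrinkage, the threshold and the sets included. Slides were also considered as batches. Slides 1 to 3 hold arrays of the other 3 types in mixture and were scanned together, and slide 4 holds all 4 DexCHX vs CHX arrays and was scanned separately.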

Results

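The data comprised log2 ratios of 21288 genes on 16 two-colour arrays, 4 for each of 4 comparisons, from 4 independent sets of Arabidopsis inflorescences. The plants lacked functional AP1 and CAL and carried AP1-GR, an AP1 fusion protein that dexamethasone activates. The share of probes well above background lay between 48.6% and 58.5% in Cy3 and between 51.1% and 79.9% in Cy5. Values are log2 ratios ± SE of the limma model with n = 4 sets, and adjusted p values are from limma. The residual spread behind the SE was estimated per gene from all 16 arrays together. The SE is therefore not the spread over the 4 sets of a comparison. Sets were less alike in DexCHX vs CHX (r across genes from -0.108 to 0.474) than in Dex vs Mock (0.37 to 0.588). Fits to the 4 arrays alone called 252 and 2617 genes. SE and p may thus be too small for DexCHX vs CHX and too large for Dex vs Mock. No plants without the transgene were included, so the comparisons do not separate the effect of AP1-GR from that of dexamethasone itself.

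Dex vs Mock asked which genes change within 3 h of AP1-GR activation. The shoot identity gene TFL1, which holds meristems in a shoot state, fell by 2.23 ± 0.17 (adjusted p = 4.53e-06, lower in 4 of 4 sets). LSH1, of a family of light-response and boundary regulators, fell by 2.30 ± 0.12 (adjusted p = 1.56e-07, lower in 4 of 4 sets). The meristem size regulators FAF2, FAF3 and FAF1 fell by 2.13 ± 0.14, 1.87 ± 0.33 and 1.56 ± 0.24. FD, the bZIP partner of the flowering signal FT, fell by 1.64 ± 0.15, and the flowering-promoting factor SPL9 by 1.36 ± 0.21. In the other direction BT1, encoding a BTB and TAZ domain scaffold protein, rose by 2.91 ± 0.29 (adjusted p = 3.9e-05, higher in 4 of 4 sets), a fold of 7.52. Its relative BT2 rose by 1.41 ± 0.20, SEN1 (AT4G35770), a gene induced in the dark and in senescence, by 1.43 ± 0.25, and the actin-binding factor gene ADF9 by 1.26 ± 0.11. The remaining genes among the 10 with the largest rise were AT2G32150 (1.76), AT2G33830 (1.64), AT2G17880 (1.54), AT2G20670 (1.39), AT1G15330 (1.29) and AT2G05540 (1.25). The remaining genes among the 10 with the largest fall were the desaturase gene ADS4 (-1.97), the expansin gene EXPA10 (-1.58) and AT1G09310 (-1.42).

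Among the lists, the flowering time and shoot identity genes were lower as a group, with 10 of 27 measured members called lower and 0 higher. Adjusted over the list alone, 13 were lower and 1 higher. The camera adjusted p was 9.08e-09. The call was lost with an estimated correlation (adjusted p = 0.282) and kept in fry (adjusted p = 0.000884). With an estimated correlation no list was called in any comparison, not even the stress genes in CHX vs Mock, where all 31 rose. SPL15 of the flowering time list had a ratio of -1.09 ± 0.19 in Dex vs Mock. Nuclear photosynthesis genes were higher as a group, with 5 of 17 called higher and 13 adjusted over the list alone (camera adjusted p = 5.48e-09, and adjusted p = 0.282 with an estimated correlation). The light-harvesting genes LHCB2.1, LHCA4, LHCA1 and LHCB4.1 rose by 1.07 ± 0.19, 0.60 ± 0.10, 0.55 ± 0.12 and 0.43 ± 0.11. Clock genes were higher as a group, although only RVE1 (0.75 ± 0.17) was called among 13, and 3 adjusted over the list alone (camera adjusted p = 0.000685, and adjusted p = 0.466 with an estimated correlation). Ribosomal protein genes were lower as a group with 0 of 7 called and 2 lower adjusted over the list alone (camera adjusted p = 0.0203, and adjusted p = 0.614 with an estimated correlation). In fry the photosynthesis (adjusted p = 0.00197) and clock lists (0.0241) were called, and the ribosomal list was not (0.133). Fry also called the cytokinin list lower (0.00231), which camera did not (0.0503).

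The floral identity list held 2 called members of 18, both higher, adjusted over the list alone 2 higher and 3 lower (camera adjusted p = 0.216). LFY, which specifies floral meristems, rose by 0.49 ± 0.11. The petal and stamen identity gene AP3 rose by 0.76 ± 0.20, with per-set values from 0.11 to 1.56 and the Mock RNA well above background on 1 of 4 arrays, and its call was lost under 9 of the alternatives. AP1 itself fell by 0.55 ± 0.13 (adjusted p = 0.0258, lower in 4 of 4 sets), a call that was lost under 5 of the alternatives, among them without the Dex vs Mock array of set 3. Whether the AP1 probe also reads the transgene was not checked. CAL had a ratio of -0.29 ± 0.10 and was not called (adjusted p = 0.131). In the meristem and boundary list 3 members were higher and 5 lower of 28 (camera adjusted p = 0.407). There the boundary gene LOF1 fell by 1.22 ± 0.09, the homeobox gene KNAT1 by 0.58 ± 0.11 and BOP1 by 0.47 ± 0.07, while the homeobox gene ATH1 rose by 0.60 ± 0.07. Of 23 polarity and TCP genes PHV fell by 0.88 ± 0.11, AS1 fell by 0.41 ± 0.09 and TCP2 rose by 0.45 ± 0.09. Among hormone genes, the DELLA repressor genes RGL2 (0.89 ± 0.06) and GAI (0.48 ± 0.10) rose, and RGL1 (-0.73 ± 0.13) fell. The cytokinin genes CKX6 (-0.75 ± 0.08), ARR7 (-0.55 ± 0.13) and LOG1 (-0.44 ± 0.11) fell. The brassinosteroid genes BR6OX2 (0.33 ± 0.07) and BAS1 (0.29 ± 0.07) and the auxin response gene IAA2 (0.67 ± 0.14) rose. No member of the jasmonate, heat shock, vascular, stamen or reference lists was called, and 1 each of the stress (TCH4, 1.08 ± 0.23), mitotic (CYCD3;1, -0.31 ± 0.06) and epidermal (GL2, -0.55 ± 0.13) lists.

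In all, 1050 genes were called in Dex vs Mock, 501 higher and 549 lower, of which 60 changed at least 2-fold. The median ratio of genes called higher was 0.42, 0.39 and 0.43 in the arrays of slides 1, 2 and 3, and that of genes called lower was -0.44, -0.47 and -0.46, in genes chosen on all slides together. The count depends on the arrays included. Without the Dex vs Mock array of set 3, which had the largest dye correction of the 16 arrays, 385 genes were called, of which 381 were among the 1050. No other Dex vs Mock array was left out singly. Without set 3 the count was 333, and without another set between 432 and 616. It was 414 with median centring in place of loess, where the balance turned to 291 higher and 123 lower, and 2617 with the 4 arrays fitted alone.

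**Figure D1:**
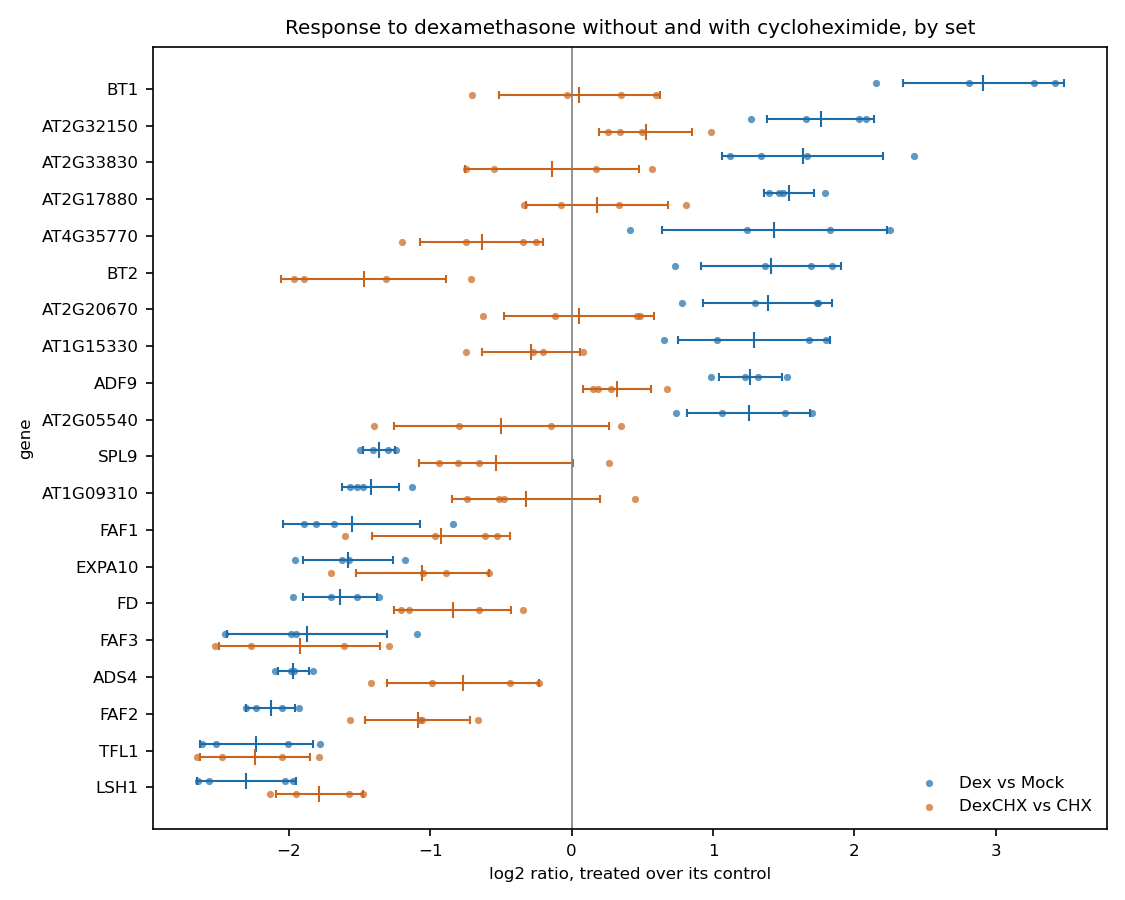
Log2 ratios (x axis, treated over its control) of the 20 genes with the largest changes in Dex vs Mock (y axis), in Dex vs Mock (blue) and DexCHX vs CHX (orange). Points are the 4 sets and bars the mean ± SD over sets. BT1 had a mean of 2.91 without and 0.05 with cycloheximide, and TFL1 -2.23 and -2.24.

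DexCHX vs CHX asked which genes respond to AP1-GR activation when protein synthesis is inhibited on both sides. TFL1 fell by 2.24 ± 0.17 (adjusted p = 1.97e-06, lower in 4 of 4 sets), LSH1 by 1.78 ± 0.12 and FAF3 by 1.92 ± 0.33. AT5G18600 fell by 1.80 ± 0.09 (adjusted p = 7.08e-08, lower in 4 of 4 sets). The monooxygenase gene FMO fell by 1.80 ± 0.18, the phytol kinase gene VTE5, of tocopherol synthesis, by 1.70 ± 0.11, and AT4G21870 by 1.67 ± 0.12. The indole glucosinolate gene CYP81F2 fell by 1.60 ± 0.21, the sucrose transporter gene SUC1 by 1.59 ± 0.12 and the defence regulator gene ORA59 by 1.57 ± 0.15. The largest rise was that of GA2OX1, encoding a gibberellin-inactivating enzyme, at 1.87 ± 0.28 (adjusted p = 0.00109, higher in 4 of 4 sets), with the CHX RNA well above background on 2 of 4 arrays. JRG21, a jasmonate-regulated gene, rose by 1.46 ± 0.19, and the homeobox gene WOX12 by 1.07 ± 0.15. ATSDI1 (1.76 ± 0.45), AT3G13310 (1.58 ± 0.41), AT1G23110 (1.20 ± 0.27), the stamen gene MYB21 (1.17 ± 0.28), PHT3;2 (1.16 ± 0.26), AT2G22760 (1.13 ± 0.29) and AT1G52900 (0.98 ± 0.15) also rose, and the call of each was lost under at least 4 of the alternatives.

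Flowering time and shoot identity genes were again lower as a group, with 9 of 27 called lower and 0 higher, and 12 lower adjusted over the list alone (camera adjusted p = 7.65e-09, and adjusted p = 0.282 with an estimated correlation). FD fell by 0.84 ± 0.15, and TEM2 and TEM1, repressors of the flowering signal FT, by 0.85 ± 0.20 and 0.80 ± 0.09. Rapid stress-response genes were lower in camera, with 4 of 31 called and 7 adjusted over the list alone (camera adjusted p = 0.00154, and adjusted p = 0.645 with an estimated correlation). Those 4 were the cold response regulators CBF2 (-1.26 ± 0.15) and CBF1 (-0.76 ± 0.18) and the ubiquitin ligase genes PUB23 (-0.86 ± 0.23) and PUB22 (-0.82 ± 0.20). CBF1 had a ratio of -1.74 in set 6, far from the other sets. Auxin genes were lower as a group (camera adjusted p = 0.0369, and adjusted p = 0.614 with an estimated correlation), with PID higher (0.35 ± 0.08) and IAA20 lower (-0.42 ± 0.10) of 20, and 2 higher and 8 lower adjusted over the list alone. Photosynthesis genes were higher as a group with 0 of 17 called, and 0 adjusted over the list alone (camera adjusted p = 0.00144, and adjusted p = 0.582 with an estimated correlation). In fry the flowering time list was called (adjusted p = 0.00192), and the stress, auxin and photosynthesis lists were not (0.295, 0.12 and 0.12). Fry also called the cytokinin list lower (0.00878) and the brassinosteroid list higher (0.035). The group calls of the stress, auxin and photosynthesis lists rest on the array of set 6, which runs against the cycloheximide effect, and were lost without it (camera adjusted p = 0.19, 0.341 and 0.274), while that of the flowering time list was kept (2.7e-13) and the floral identity list was then lower (0.00287). With an estimated correlation no list was called in this fit either (adjusted p = 0.244 for the flowering time and 0.535 for the floral identity list). The mean of the stress list was -0.21, -0.05, -0.25 and -0.43 in sets 3 to 6. LOF1 fell by 1.39 ± 0.09, BOP1 by 0.53 ± 0.07 and PHV by 0.80 ± 0.11, whereas PUCHI (0.58 ± 0.08), the stem cell gene WUS (0.54 ± 0.10) and TCP2 (0.66 ± 0.09) rose. Of the floral identity genes AP2 rose (0.42 ± 0.09) and the carpel gene CRC fell (-0.78 ± 0.19), each in 3 of 4 sets. CRC had a ratio of 0.22 in set 6, and its call was lost without set 3 (-0.50, adjusted p = 0.323). Cytokinin genes LOG1, CKX6 and ARR9 fell by 0.97 ± 0.11, 0.83 ± 0.08 and 0.48 ± 0.09, and BR6OX2, of brassinosteroid synthesis, rose by 0.81 ± 0.07. AP1 had a ratio of -0.49 ± 0.13 (adjusted p = 0.0577, lower in 3 of 4 sets) and CAL one of -0.19 ± 0.10 (adjusted p = 0.444).

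In all, 783 genes were called in DexCHX vs CHX, 174 higher and 609 lower, of which 65 changed at least 2-fold. All 4 arrays sat on 1 slide that held no other type, so no value within another slide can be had, but the indirect estimate from slides 1 to 3 called 141 genes, 135 of them among the 783. The count was 414 with the software's processed intensities, 328 with median centring, 252 with the 4 arrays fitted alone, 406 without set 3 and 395 without set 5, and 1510 in a model of RNA levels, which also uses the other arrays.

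Whether the response to dexamethasone differs with cycloheximide was tested as the difference of both ratios, which share no RNA. BT2 and BT1 had the largest differences, -2.88 ± 0.28 (adjusted p = 0.000284, lower in 4 of 4 sets) and -2.86 ± 0.41 (adjusted p = 0.00499, lower in 4 of 4 sets). BT2 rose in Dex vs Mock and fell by 1.47 ± 0.20 in DexCHX vs CHX, whereas BT1 had a ratio of 0.05 ± 0.29 there. SEN1 (AT4G35770, -2.07 ± 0.35), AT5G18600 (-1.90 ± 0.13) and AT2G33830 (-1.77 ± 0.32) were the next largest negative ones. AT2G05540, AT1G15330, AT2G17880, AT2G32150 and ADF9, all higher in Dex vs Mock, also had negative differences. On the positive side were AT1G23110 (1.93 ± 0.38), CYP96A15 (1.72 ± 0.28), a wax synthesis gene, JRG21 (1.49 ± 0.27), AT1G04770 (1.34 ± 0.23) and AT5G53048 (1.19 ± 0.26). The lower ratio of TFL1, LSH1, FAF3 and FD did not pass this test, while FAF2 did (1.04 ± 0.20). Among the lists, the rapid stress (adjusted p = 7.61e-05), ribosomal (0.000811), auxin (0.00926), photosynthesis (0.0163), clock (0.02) and heat shock (0.0396) genes differed as groups in camera. All of these were negative except the ribosomal genes, each held at most 4 called members, and with an estimated correlation the smallest adjusted p was 0.582. Fry called no list for the difference, with a smallest adjusted p of 0.07. Without the DexCHX vs CHX array of set 6 the auxin and heat shock calls were lost (camera adjusted p = 0.0578 and 0.274), and those of the stress (0.012), ribosomal (0.0106), clock (0.00687) and photosynthesis genes (5.15e-05) were kept, and gibberellin genes were then lower (0.0436). With an estimated correlation none of these calls was left in this fit, where the smallest adjusted p was 0.336.

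The difference was called in 293 genes, 61 positive and 232 negative, and in 512 with the set as a fixed block and 459 with a random one. It included 121 of the 501 genes higher and 45 of the 549 lower in Dex vs Mock. The median ratio of the genes called higher was 0.41 in Dex vs Mock and 0.04 in DexCHX vs CHX, and that of genes called lower was -0.45 and -0.25. Both comparisons called 37 genes higher, against 4.095 expected if independent, and 213 lower, against 15.7 expected. Another 18 genes, BT2 among them, were higher in Dex vs Mock and lower in DexCHX vs CHX, against 14.3 expected, and 0 the other way, against 4.49. Fisher's exact test, one-sided, gave p = 7.29e-25, 1.99e-192, 0.192 and 1 for these 4 counts, although genes are not independent replicates. Across all genes the ratios had r = 0.286, 1 of 2 relations between mean ratios that were computed, beside r and slopes across genes of single sets and arrays. Without set 3 the difference was called in 25 genes, without set 5 in 30, without set 6 in 101 and with the indirect estimate from slides 1 to 3 in 20, 19 of them among the 293. The count called the same way in both, 250, fell to 85 without set 3.

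**Figure D2:**
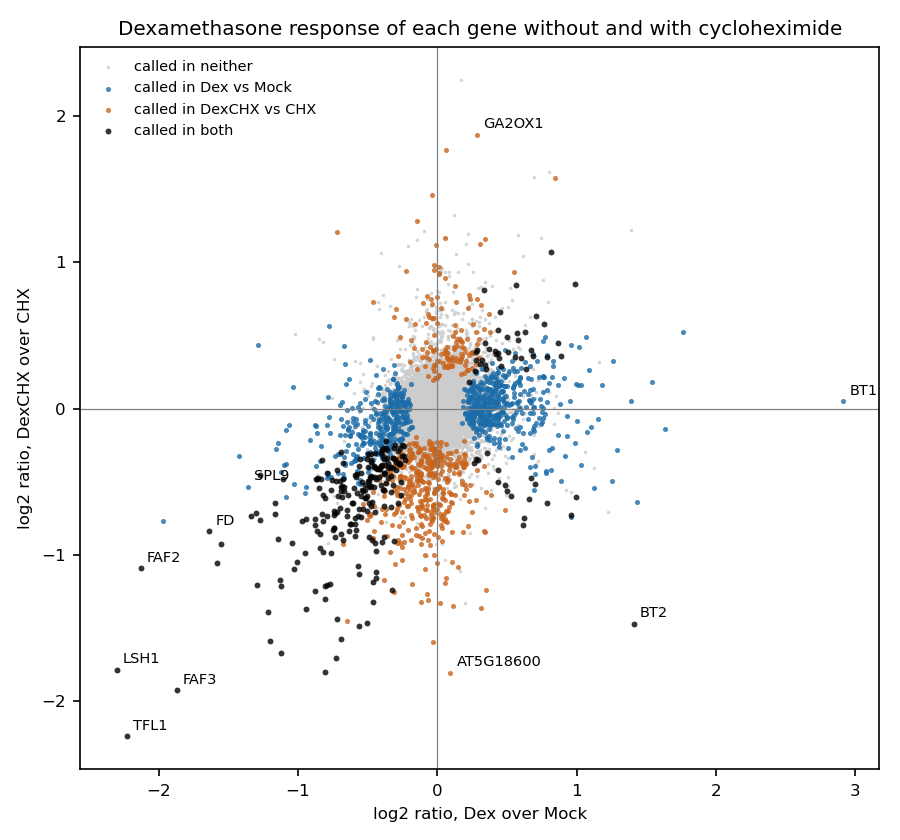
Log2 ratio of each of 21288 genes in Dex vs Mock (x axis) and DexCHX vs CHX (y axis), coloured by the comparisons in which it was called. The lower left quadrant holds 213 of the 250 genes called the same way in both, and BT1 lies at 2.91 and 0.05.

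CHX vs Mock shows what cycloheximide does alone. The largest rises were those of AT1G30190 (8.89 ± 0.23, adjusted p = 1.12e-13, higher in 4 of 4 sets) and CML37, encoding a calmodulin-like protein (8.22 ± 0.23). MYB3R2 (8.08 ± 0.23), the calcium pump gene AT3G22910 (7.93 ± 0.25), the zinc finger genes ZAT7 (7.80 ± 0.29) and ZAT10 (7.74 ± 0.23), and the immune regulator gene CBP60G (7.76 ± 0.21) followed. The syntaxin gene SYP122 (7.69 ± 0.16), AT2G20142 (7.69 ± 0.21) and NAC036 (7.65 ± 0.21) completed the 10. Falls were smaller, led by AT4G10270 (-3.56 ± 0.60, adjusted p = 9.09e-05, lower in 4 of 4 sets) and TIP2, an aquaporin gene (-2.78 ± 0.25). The others were AT5G57785 (-2.62), the cell wall gene XTH6 (-2.57), AT1G29270 (-2.50), the homeobox gene AtHB23 (-2.40), AT3G03270 (-2.40), AT1G12805 (-2.35), the arabinogalactan protein gene AGP12 (-2.27) and the chlorophyllase gene CLH1 (-2.27).

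All 31 rapid stress-response genes rose, with a median of 5.69, and also adjusted over the list alone (camera adjusted p = 4.89e-21, and adjusted p = 0.282 with an estimated correlation). ZAT12 (7.25 ± 0.29), WRKY40 (7.24 ± 0.20) and WRKY46 (6.98 ± 0.19) were among them. Auxin genes rose, with 17 higher and 1 lower of 20 (camera adjusted p = 1.23e-06, and adjusted p = 0.282 with an estimated correlation). The early auxin response genes GH3.1 and IAA3 rose by 7.23 ± 0.19 and 6.09 ± 0.17, the former with the Mock RNA above background on 3 of 4 arrays, and the auxin synthesis gene YUC1 by 4.12 ± 0.16. Of 19 jasmonate genes 14 were higher and 2 lower (camera adjusted p = 7.61e-05, and adjusted p = 0.582 with an estimated correlation), with LOX4 (6.36 ± 0.20), LOX3 (6.31 ± 0.22), ORA47 (5.62 ± 0.17) and JAZ5 (5.43 ± 0.33). Of 13 cytokinin genes 8 were higher and 2 lower (camera adjusted p = 0.0179, and adjusted p = 0.282 with an estimated correlation). ARR7 rose by 2.57 ± 0.13. ARR17 had a fitted ratio of 2.40, but its Mock RNA was not above background on any array, so the size of its rise is uncertain. Heat shock genes were higher in 6 of 8 (camera adjusted p = 0.0103, and adjusted p = 0.517 with an estimated correlation), with DREB2A at 2.87 ± 0.21 and HSFA2 at 2.80 ± 0.10. Each of these lists had the same counts adjusted over the list alone, and fry called each, with adjusted p of at most 9.68e-08.

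Groups that were lower with cycloheximide alone were the flowering time list with 18 lower and 4 higher of 27 (camera adjusted p = 0.0163), photosynthesis with 12 of 17 (0.00356), mitosis with 13 of 17 (0.00784) and ribosomal proteins with 6 of 7 (0.0181). Each count was the same adjusted over the list alone, and each call was lost with an estimated correlation (adjusted p = 0.614). Fry called the photosynthesis (adjusted p = 3.99e-05), mitosis (0.000374) and ribosomal lists (0.000122), but not the flowering time list (0.0988). SPL3 (-2.26 ± 0.26), LHCB1.3 (-1.36 ± 0.15), CYCB1;1 (-0.94 ± 0.10) and BBC1 (-1.30 ± 0.11) had large falls in these lists, whereas TEM2 (7.60 ± 0.20) and TEM1 (4.14 ± 0.09) of the flowering time list rose. RPL18AA of the ribosomal list is uncertain, since its probes were called in opposite directions. The remaining lists were not called as groups in camera. Fry called the polarity (adjusted p = 0.000226), brassinosteroid (0.00118), epidermal (0.000843) and reference lists (0.000829) lower. Counts higher and lower were 4 and 10 of 18 floral identity genes (adjusted p = 0.407), 10 and 13 of 28 meristem genes (0.888), 3 and 13 of 23 polarity genes (0.07), 5 and 5 of 18 gibberellin genes (0.985) and 2 and 4 of 6 brassinosteroid genes (0.407). They were 6 and 2 of 13 clock genes (0.667), 2 and 3 of 9 vascular (0.933), 0 and 6 of 9 epidermal (0.0514) and 2 and 2 of 5 stamen markers (0.963). In the meristem list, with a median of -0.16, a mean of 0.01 and a negative test, the stem cell gene WUS rose by 1.46 ± 0.10 and DRNL by 1.79 ± 0.10. Of 7 reference genes, ACT8 (-0.97 ± 0.10), ACT2 (-0.86 ± 0.12), UBC21 (-0.18 ± 0.07) and EF1A4 (-0.27 ± 0.11) fell, 3 of them adjusted over the list alone (camera adjusted p = 0.178), but EF1A4 turned to 0.02 with the processed intensities.

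**Figure D3:**
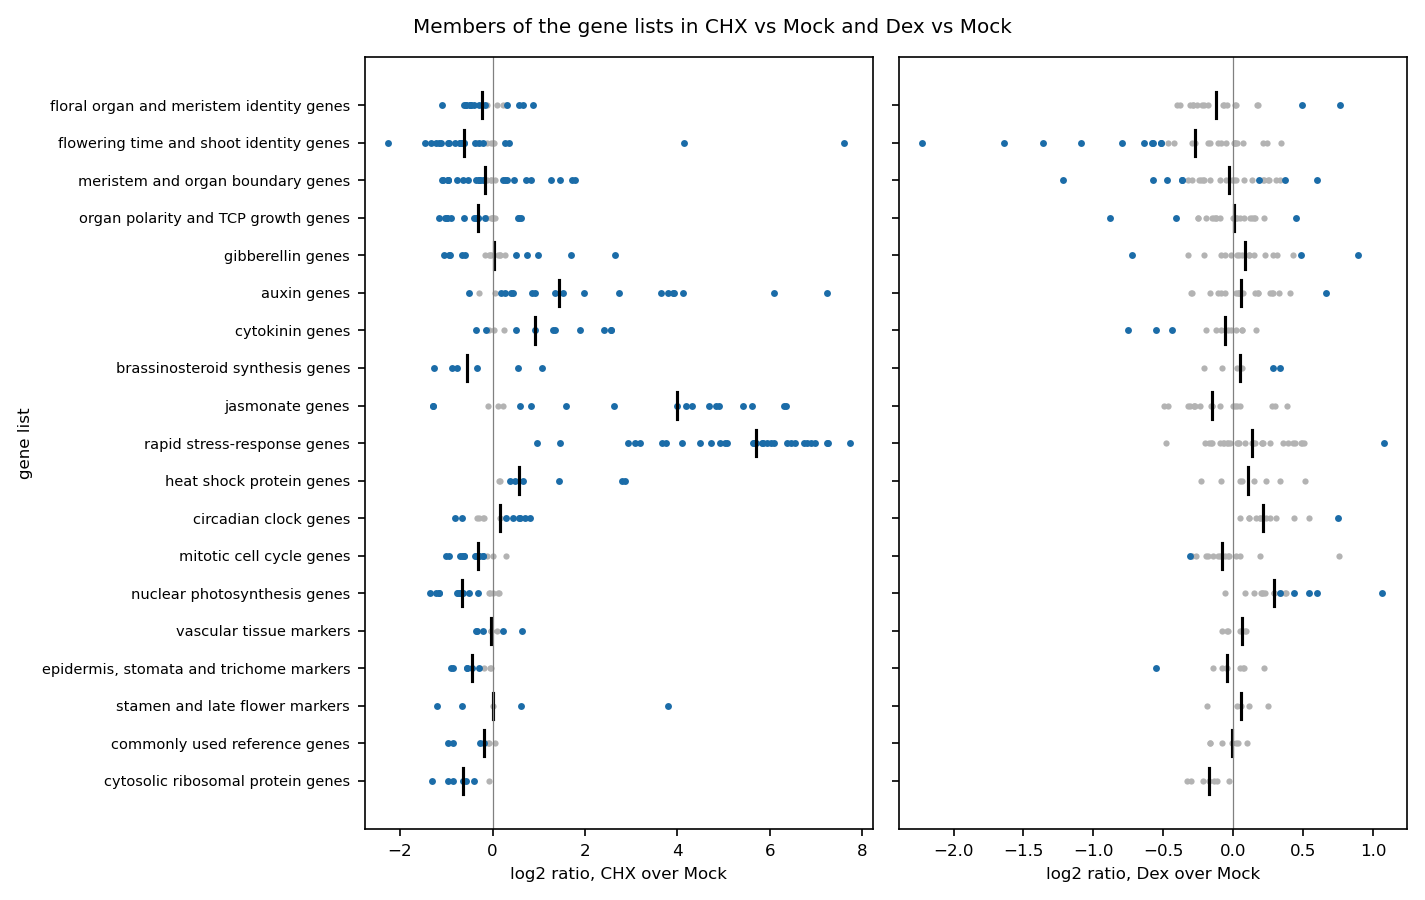
Log2 ratio (x axes) of the measured members of the 19 gene lists (y axis) in CHX vs Mock, left, and Dex vs Mock, right. Points are genes, blue where called and grey where not, and black bars are list medians. The stress-response median is 5.69 with cycloheximide, and the flowering time list reaches -2.23 in Dex vs Mock with TFL1.

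CHX vs Mock called 13649 genes, or 64.1% of those tested, 6571 higher and 7078 lower, of which 2255 rose and 742 fell at least 2-fold. Medians of genes called higher were 0.70, 0.66 and 0.63 within slides 1, 2 and 3. Those of genes called lower were -0.48, -0.52 and -0.43. These genes were chosen on all slides together, so the medians are no independent check of a slide. The median of all genes moved from -0.01 to -0.25 with the processed intensities and to -0.17 with median centring, so that small changes are relative to the scaling, and the share of called genes that were higher went from 48.1% to 35.4% and 29.2%.

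DexCHX vs Mock gave the joint effect of both compounds, and its values cannot be set against those of CHX vs Mock as independent, since both use the Mock RNA. It called 13198 genes, 6964 higher and 6234 lower, and the median of all genes moved to -0.19 with the processed intensities. The share of called genes that were higher went from 52.8% to 39.1% with these and to 64.1% with median centring, so that which direction holds more genes depends on the scaling. The largest rises were those of AT1G30190 (8.62 ± 0.23), CML37 (7.96 ± 0.23), MYB3R2 (7.83 ± 0.23), SYP122 (7.70 ± 0.16) and AT3G22910 (7.59 ± 0.25). The largest falls were those of AT1G29270 (-2.86 ± 0.26), AT4G10270 (-2.82 ± 0.60), the growth regulator gene AT5G53660 (-2.74 ± 0.20), AT5G57785 (-2.74 ± 0.24) and XTH6 (-2.73 ± 0.29). TFL1 fell by 2.39 ± 0.17 and LFY rose by 0.99 ± 0.11. All 31 rapid stress-response genes were higher (camera adjusted p = 4.71e-20, and adjusted p = 0.282 with an estimated correlation), and 21 of 27 flowering time genes were lower (camera adjusted p = 9.73e-05, and adjusted p = 0.569 with an estimated correlation). Auxin genes (15 higher and 2 lower of 20, adjusted p = 4e-05, and 0.282 with an estimated correlation) and jasmonate genes (14 higher and 2 lower of 19, adjusted p = 7.57e-05, and 0.582 with an estimated correlation) were higher as groups. Heat shock genes were higher in 5 of 8 (adjusted p = 0.0413, and 0.582 with an estimated correlation). Polarity (13 lower and 4 higher of 23, adjusted p = 0.0313), mitotic (13 of 17, 0.00727), photosynthesis (10 of 17, 0.0282) and epidermal genes (7 of 9, 0.0437) were lower as groups, each with an adjusted p = 0.614 with an estimated correlation. Counts adjusted over the list alone were the same, except 16 higher for jasmonate. Fry called each of these lists, with adjusted p of at most 0.0014. It also called the floral identity, cytokinin, clock, stamen, reference and ribosomal lists, which camera did not. Medians of genes called higher were 0.76, 0.67 and 0.49 within slides 1, 2 and 3. Those of genes called lower were -0.51, -0.63 and -0.38, again in genes chosen on all slides together.

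The indirect ratio, DexCHX vs Mock minus CHX vs Mock, measures the same difference as DexCHX vs CHX on other arrays, with the same DexCHX and CHX RNA in each set. Across all genes both had r = 0.804, and 0.626, 0.411, 0.689 and 0.819 in sets 3 to 6. In limma 0 genes differed between them, and 255 at an unadjusted p under 0.05, fewer than chance alone gives. The model treats arrays that share RNA as independent, which makes its error too large here, so the 0 does not show that both ratios are equal.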

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

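The tests of the response retained under cycloheximide and of the set 6 array were chosen only after the result was seen.

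The response to dexamethasone differed with cycloheximide in 293 genes by a test of the difference itself. Of the 35 splits of the 8 arrays into 4 and 4, only the real one called as many, the highest other calling 1. The set pairs the arrays, however, and only 8 of these splits part all 4 sets as the real one does, too few for a share under 0.05, with 293 genes in the real one and 1 in the highest other. For the counts of each comparison, 1050, 783, 13649 and 13198, turning the signs of arrays gives 8 splits, too few for a share under 0.05. Only 1 split, the real one, called as many in each, with the highest other at 0, 0, 2 and 7.

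The genes higher in Dex vs Mock kept little of their rise under cycloheximide, with a median of 0.41 without and 0.04 with it. To avoid picking genes by a high chance value, 501 were chosen in 2 sets and measured in the other 2. Their median in Dex vs Mock there averaged 0.391, against 0.09 and 0.01 in DexCHX vs CHX, which argues against that explanation, and in slides 1 to 3 alone they retained 0.157 of it, which argues against a difference between slides. Genes not called in CHX vs Mock, 136 and 132 of the 501, retained 0.0963 (0.233 and -0.0399 in either choice of sets). For these genes, this argues against the change that cycloheximide itself makes in a gene as the source of the loss. It says nothing about genes that cycloheximide changes, such as BT2 (2.65 in CHX vs Mock) and SEN1 (1.01). A candidate explanation, as a hypothesis found and tested on the same data, is that many of the rises within 3 h may need newly made proteins, whereas genes chosen as lower retained 0.449 and 0.821 of their response. The count of 293 genes depends on the sets included, with 25, 258, 30 and 101 genes without set 3, 4, 5 or 6.

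The DexCHX vs CHX array of set 6 ran against the cycloheximide effect of the other sets, with a slope across genes of -0.176, against 0.064, 0.00751 and -0.0033 in sets 3 to 5. Measured on other arrays as DexCHX vs Mock minus CHX vs Mock, the slope of set 6 was -0.161, against 0.0261, -0.0694 and -0.0451. An error of that array or its slide would leave the slope on other arrays within the range of the other sets. The value lies below that range, but by less than the range is wide, so the rule set for this test did not decide. The indirect ratio of set 6, from arrays on slide 3, had r = -0.566 with the cycloheximide effect, against 0.0991, -0.229 and -0.164 in sets 3 to 5. Direct and indirect ratios had r = 0.819 in set 6, against 0.626, 0.411 and 0.689. The r values were not part of that rule, and those with the cycloheximide effect restate the slope relative to the spread. What the values show is that a slope below those of the other sets recurred in set 6 on arrays of slide 3. With 4 sets, this argues against that array or its slide as the only source of the slope, and the rule stays undecided. The values are consistent with a weaker response to cycloheximide in the DexCHX RNA of set 6, whose slope in DexCHX vs Mock was 0.753 against 1.03, 1.06 and 0.847, a hypothesis formed on these same data, and why it would be weaker was not tested. Leaving out that array gave 646 genes in DexCHX vs CHX and 241 for the difference, chosen after seeing the data.

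Named genes whose response was more negative with cycloheximide by the same test were BT2 (-2.88), BT1 (-2.86), SEN1 (AT4G35770, -2.07), AT5G18600 (-1.90), AT2G33830 (-1.77), AT2G05540 (-1.75), AT1G15330 (-1.58) and CYP81F2 (-1.56). With smaller values these were AT2G17880 (-1.36), AT2G32150 (-1.24), CBF2 (-1.19), HSFA7A (-1.17), IAA2 (-1.07), VTE5 (-0.98), ADF9 (-0.94), ORA59 (-0.88), IAA30 (-0.82), IAA20 (-0.70), TEM1 (-0.69), BAS1 (-0.54) and RGL2 (-0.53). More positive ones were AT1G23110 (1.93), CYP96A15 (1.72), JRG21 (1.49), AT1G04770 (1.34), AT5G53048 (1.19), FAF2 (1.04), AT1G52900 (1.00), RPSAb (0.52), BR6OX2 (0.48) and PID (0.46).

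In 18 of 367 groups of 4 sets for a named gene, 4.90%, 1 set stood far from the others, and chance alone gives about 1 in 20. In Dex vs Mock these were HSP101 (0.083), AMS (-0.52) and BBC1 (-0.52) in set 3, LHCA4 (0.76) in set 5, and RPSAb (-0.093), TPD1 (0.13) and RVE1 (1.01) in set 6. In DexCHX vs CHX they were TMM (0.61) and CBF1 (-1.74) in set 6. In CHX vs Mock they were CLH1 (-1.86), HSFA2 (2.99) and PSBO1 (-0.99) in set 3, LOX3 (7.58) in set 4, and LHCB1.3 (-0.89), IAA2 (3.496) and YUC1 (3.79) in set 5. In the difference they were AT2G33830 (-0.55) in set 4 and PUCHI (0.72) in set 5.

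Probes without a locus name, which no comparison uses, also changed. Of 2236 tested, 2 were called in Dex vs Mock, 12 in DexCHX vs CHX, 308 in CHX vs Mock and 322 in DexCHX vs Mock.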

How the results depend on the processing

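Leaving out single arrays and using slides 1 to 3 alone were chosen after seeing the data. Of 297 called values of named genes, 202 stayed called in the same direction under every alternative run for them, and 95 lost the call under at least 1. EF1A4 in CHX vs Mock reversed to 0.02 with the processed intensities and with the deposited value table, and RPL18AA, whose probes disagree, to 0.025 and 0.083 (CHX vs Mock, DexCHX vs Mock) with the mean of probes. Unless stated, the cause was not tested. Counts for DexCHX vs CHX (783), the difference (293) and r of the direct with the indirect ratio (0.804) became 414, 119 and 0.584 with processed intensities and 417, 120 and 0.584 with the value table. Median centring gave 414 for Dex vs Mock (1050), 328, 93, 64 for genes called the same way in both (250) and r = 0.427. The difference was 513 with a slide block, 512 and 459 with a fixed and a random set block, and 570 in a model of RNA levels, which gave 1510 for DexCHX vs CHX. With only the arrays of the type the counts were 2617, 252 and 131 for Dex vs Mock, DexCHX vs CHX and both. Leaving out 1 set gave 333 to 616 for Dex vs Mock, 395 to 777 for DexCHX vs CHX, 25 to 258 for the difference and 85 to 189 for both, with fewer samples by construction. Without the Dex vs Mock array of set 3 the counts were 385, 711, 89 and 148, and without the DexCHX vs CHX array of set 6 they were 1226, 646, 241 and 237. Slides 1 to 3 alone gave 141, 20 and 84 for DexCHX vs CHX, the difference and both. A threshold of 1 on the log2 scale lowered the counts by construction to 60, 65, 2997, 2804, 64 and 13. Of 95 list tests 32 were called, 0 with an estimated correlation, 34 with fry in 1 direction and 63 in either, and 30 without the DexCHX vs CHX array of set 6. The model of RNA levels and the threshold of 1 give no value for r, and scaling between arrays after loess leaves log ratios as they are. The means of the lists called kept their sign under every scaling run. Counts for CHX vs Mock and DexCHX vs Mock stayed within 1.5 times under all but the threshold of 1. Signal over background limits ratios of dim genes such as AP3, GA2OX1 and ARR17.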

Other observations

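The tests of the gene list in Dex vs Mock and in DexCHX vs CHX were written down before their results were seen, and those in CHX vs Mock and of the difference were not and count as chosen only after the result was seen. The list was drawn up after the genes with the largest changes were known, and those genes were left out of its tests.

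Genes known to be induced by darkness or low sugar were looked at as a group, because BT2, SEN1 (AT4G35770) and AT2G33830, a dormancy-associated gene, were among the largest rises in Dex vs Mock. Of 20 such genes, 16 were measured and not already named, and 9 of them were higher in Dex vs Mock and 0 lower. The asparagine synthetase gene ASN1 rose by 0.96 ± 0.18 (adjusted p = 0.00521), BGAL4 by 1.18 ± 0.22 and the trehalose phosphate synthase gene TPS8 by 0.70 ± 0.17. In DexCHX vs CHX 5 were lower and 0 higher. Of these, ASN1 (-0.73 ± 0.18) and KMD1 (-0.64 ± 0.17) were among the 9 higher in Dex vs Mock. DIN10 (-0.88 ± 0.14), MIOX2 (-0.93 ± 0.22) and BCAT2 (-0.79 ± 0.19) were not, with ratios of 0.007, -0.67 and -0.12 in Dex vs Mock. In CHX vs Mock 11 were higher and 0 lower.

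The hypothesis that these genes rise as a group passed its test in Dex vs Mock, with a mean of 0.39 and camera p = 5.07e-07 (p = 0.0454 with an estimated correlation), and set means of 0.35, 0.17, 0.49 and 0.57 in sets 3 to 6. The p values of this list are unadjusted, unlike those of the 19 lists. In Dex vs Mock the flowering time and photosynthesis lists had unadjusted camera p = 0.0186 and 0.0163 with an estimated correlation, which adjustment over 95 tests took to 0.282. The list was prompted by rises on these same arrays, and leaving 3 genes out does not make its test independent of them. With cycloheximide the hypothesis failed the same test. The mean was -0.34 with camera p = 5e-06 in the direction of a fall (p = 0.065 with an estimated correlation), and set means were -0.44, -0.36, -0.46 and -0.10. The difference of both responses had a mean of -0.73 (camera p = 1.23e-13, and p = 0.00671 with an estimated correlation). Cycloheximide alone raised the list, with a mean of 0.83 (camera p = 0.00185, and p = 0.19 with an estimated correlation). In DexCHX vs Mock the set means were 0.77, 0.65, 0.23 and 0.56. The fall in DexCHX vs CHX is thus measured from a raised level, and a lost response cannot be told apart from an effect of that level. A response like that to low carbon supply may accompany AP1-GR activation in the absence of cycloheximide, but sugar levels were not measured, and an effect of dexamethasone without AP1-GR stays open.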
